A study of Setaria viridis with 15 samples.

How the data were processed

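Shoots of Setaria viridis, a small C4 grass, were sequenced after 7 days of culture in sealed plates under a 12 h photoperiod. Per the labels' protocols, total RNA was taken with a column kit (SV Total RNA, Promega) and libraries were made with a stranded total RNA kit (TruSeq). The submitters' processing notes name FastQC, Trimmomatic, HISAT2, featureCounts and DESeq2 1.6.3, with no role or order. The genome build, annotation, and strand setting of the counting are not given in the sources used here, so antisense, overlapping and near-identical genes may share counts.

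The authors deposited 1 table of raw counts per gene, whole numbers with no normalization, for 28032 genes and 15 libraries, and 6 tables of their own pairwise comparisons. In those deposited tables the authors give a mean normalized signal per gene, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value, several lines per gene. The p-value column held the same values as the adjusted one in 100% of lines where both were given. The set of libraries behind the deposited signal is not given in the sources used here. Gene descriptions, present for 23214 genes, came from the authors' deposited tables, and 26304 gene identifiers were found in a reference table of the assembly Setaria_viridis_v4.0, used for names. Results not said to come from the authors' deposited table were computed from the counts.

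Libraries were grouped by treatment and replicate number as labelled: 4 controls, 4 with AI2.2-A, 3 with CTB P6B8 and 4 with MTS P5D6. The 21 pairs of libraries within groups had a chi-square per degree of freedom of 2.69 to 21.4 over genes, so no library was a second copy of another. Of the genes, 2690 had 0 counts in all libraries, and 20310 passed filterByExpr and were tested. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F test, two-sided, all 15 libraries in one fit of 4 groups), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. CPM and log2 CPM used a prior count of 2 for principal components, correlations and distant libraries and none for the CPM printed. All 6 pairwise comparisons came from that fit, without a replicate block, since neither the labels nor the series mention one.

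44 gene lists, which held 4010 genes, were fixed by patterns on the descriptions before the data were examined, as were the tests, the alternatives and the naming rule. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset inter-gene correlation of 0.01), with adjustment over all lists and the 3 comparisons of a kind, and again with a correlation estimated per list. The directional test fry asks whether the genes of a list move one way on balance and compares them with no other genes. The patterns took in some unrelated members: phosphoglycerate kinases under photorespiration (5 tested), Rab proteins under abscisic acid (18), clock pseudo-response regulators under cytokinin (6), ATP-citrate synthases under the TCA cycle and folylpolyglutamate synthases under nitrogen.

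The naming rule took, for each isolate against control, the 6 higher and 6 lower called genes with the largest fitted log2 fold change, a mean log2 CPM of at least 1, every isolate library on one side of every control library and an informative description. It added 2 members with the smallest p in the leading direction from up to 8 lists with the smallest camera p, 3 higher and 3 lower genes for each pair of isolates, and 4 higher and 4 lower genes called with all 3 isolates. Genes with 1 to 3 counts over the controls are given as a ratio of summed counts with a 95% interval for counting error only.

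The procedure was tested on data simulated from the means and library sizes of these samples. For AI2.2-A, then CTB P6B8, then MTS P5D6, each against control, over 20310 genes, it called 37.1%, 27.9% and 29.9% of genes changed by 0.5 on the log2 scale, 81.2%, 72.7% and 76.2% of those changed by 1 and 97.1%, 91.8% and 97.0% of those changed by 2, all with the right sign. It called 0.0257%, 0.0309% and 0.0412% of unchanged genes, and the list test called the 1 moved list of 44. Far more genes were called here, so these rates may not hold. Overlaps of comparisons sharing controls were set against 20 simulations of unchanged groups and 3 splits of the controls into 2 and 2, both ways. A first version, centred on the observed control mean, removed the shared error. Each gene's true mean was then drawn anew, the same for all isolate groups.

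The alternatives were relative log expression scaling, total counts only, 2 other count filters, DESeq2 1.42.0, limma-voom with sample quality weights, fits of only the groups compared, 2 other thresholds, each replicate left out in turn, 2 kinds of replicate block, and for lists fry and an estimated correlation. Figures were drawn in Python 3.11 with matplotlib 3.10.9.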

Results

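Transcript levels were measured by RNA sequencing in shoots of the C4 grass Setaria viridis after 7 days beside 1 of 3 bacterial isolates, named MTS P5D6, CTB P6B8 and AI2.2-A, or beside an uninoculated dish as mock control. Each sealed plate held 2 seedlings on plant medium and a smaller dish of LB medium that carried 20 µL of bacterial suspension, so that seedlings and bacteria shared the air but not the medium. The series gives the response to bacterial volatile compounds as its question, and all pairwise comparisons of the 4 treatments as its plan. There were 4 control, 4 AI2.2-A, 3 CTB P6B8 and 4 MTS P5D6 libraries, labelled as biological replicates, and p-values here measure the spread between these samples as labelled. Total counts per library ran from 13852517 to 20556455 in controls, 18222557 to 23919167 with AI2.2-A, 17118899 to 25123025 with CTB P6B8 and 16755755 to 19453085 with MTS P5D6. The test covered 20310 genes.

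The first principal component of log2 CPM held 40.8% of the variance and set the 4 controls apart from all 11 isolate libraries. The second held 24.5% and ordered the isolates, with AI2.2-A at one end, MTS P5D6 at the other and CTB P6B8 between them. Replicate 4 of AI2.2-A lay at 21.2 on this component, against 45.6 to 54.3 for the other AI2.2-A libraries and 7.54 to 21.2 for CTB P6B8. Genes of the plastid genome held 0.184% of counts in CTB P6B8 replicate 3, or 46204 counts, and 0.0209% to 0.0652% in the other 14 libraries.

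**Figure D1:**
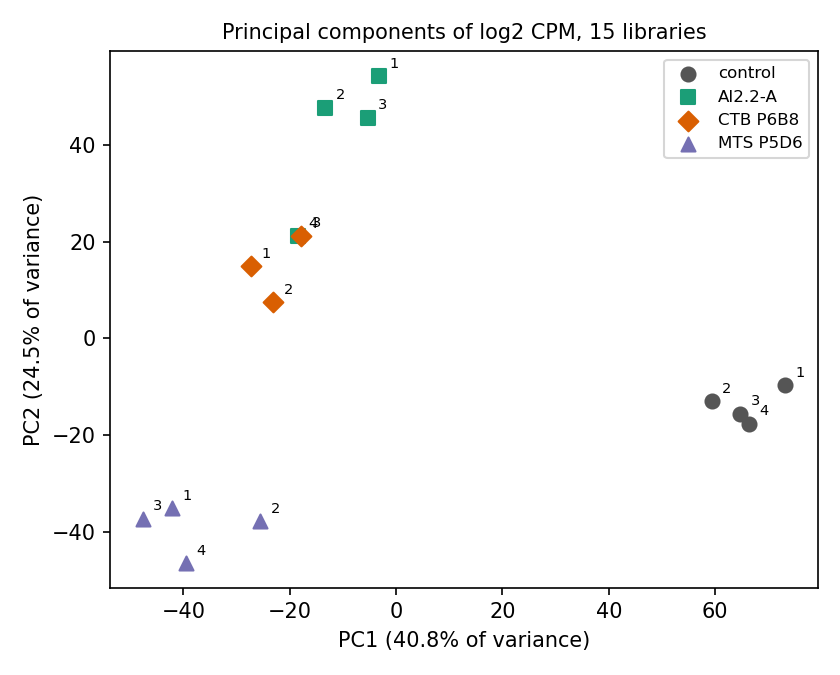
Principal components of log2 CPM of the 20310 tested genes. Each point is 1 of 15 libraries with its replicate number, the axes give PC1 (40.8% of the variance) and PC2 (24.5%), and the 4 controls lie at the right, with AI2.2-A at the top, MTS P5D6 at the bottom and CTB P6B8 between them at the left.

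Beside AI2.2-A, transcripts of fermentation enzymes rose and the main nitrate reductase transcript fell. Alcohol dehydrogenase 1 (LOC117833817, 3.59 ± 0.17), which turns acetaldehyde into ethanol, stood at 2.83 ± 0.463 in controls and 34 ± 6.98 CPM (SD, n = 4 and 4) with the isolate. Pyruvate decarboxylase 2 (LOC117836049, 2.80 ± 0.17), the step before it, stood at 5.47 ± 0.603 and 37.9 ± 3.89 CPM (SD, n = 4 and 4). NADH nitrate reductase (LOC117860413, -4.04 ± 0.36), the entry step of nitrate assimilation, fell from 853 ± 84.8 to 51.7 ± 33.5 CPM (SD, n = 4 and 4). Values in brackets after gene identifiers are log2 fold changes ± SE throughout, and list members not counted as risen or fallen were not called. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9687 genes (47.7%) changed, 4743 higher and 4944 lower, of which 1642 rose and 501 fell at least 2-fold. The higher share of calls, 49.0%, ran from 48.3% to 67.6% over 17 alternatives at that threshold and crossed 50% in 5, highest by total counts alone, where the median log2 fold change of all genes was 0.127 in place of -0.00471.

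The largest increases by the naming rule were in transcripts almost absent from controls. An ervatamin-B-like gene (LOC117833743, 8.95 ± 1.67), of a cysteine protease type, had 6 counts over the 4 control libraries, an indole-2-monooxygenase-like gene (LOC117861752, 6.52 ± 1.04), of an enzyme family in benzoxazinoid defence synthesis, had 5, and lipoxygenase 2.1 (LOC117851960, 6.28 ± 0.76), of the family that starts jasmonate synthesis, had 4. A 28 kDa phosphoprotein-like gene (LOC117850329, 6.52 ± 1.28) had 10, and fitted folds from so few counts depend on the prior count. For a proline--tRNA ligase-like gene (LOC117860973), with 3 control counts, the summed counts relative to TMM-scaled library totals were 130.2-fold (95% counting interval 44.3 to 634) higher. For NADPH:quinone oxidoreductase 1 (LOC117836940), with 2, they were 92.6-fold (95% counting interval 25.4 to 769) higher. All 6 had adjusted p from 1.07e-05 to 0.00397, but the ligase (adjusted p = 0.0683) and the phosphoprotein (0.0596) missed the threshold in limma-voom with sample quality weights. The protease stood at 7.98 without AI2.2-A replicate 1 and 9.58 without control replicate 3, the lipoxygenase at 7.70 without the latter, and the ligase at 6.16 in place of 6.81 without AI2.2-A replicate 2. The largest decreases after nitrate reductase were in carotenoid cleavage dioxygenase 8 (LOC117866430, -3.41 ± 0.18), of strigolactone synthesis, PELPK1 (LOC117836899, -3.32 ± 0.53), plasma membrane ATPase 2 (LOC117841399, -3.19 ± 0.53), a proton pump, the sugar transporter SWEET14 (LOC117866587, -2.81 ± 0.33) and bHLH162 (LOC117855913, -2.67 ± 0.36), with adjusted p from 7.31e-09 to 0.000174. Without control replicate 1 PELPK1 stood at -2.68.

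Of 8 genes of the low-oxygen response, 7 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 4.84e-12 or 0.0349 with an estimated correlation). Of the list calls in all 6 comparisons, this was the 1 that held with an estimated correlation. Besides both genes above, alcohol dehydrogenase 2 (LOC117834143, 3.07 ± 0.19), a non-symbiotic hemoglobin (LOC117840678, 3.83 ± 0.35) and lactate dehydrogenase A (LOC117849186, 3.95 ± 0.48) rose, and another non-symbiotic hemoglobin-like gene (LOC117850458, -0.47 ± 0.18) fell. These 4, list members introduced with 'for example' or 'led by', and members that moved against their list, here and in the other comparisons, were chosen after their values were seen, the examples as large changes at a mean log2 CPM of at least 3. Among 184 cytosolic ribosomal proteins, 119 rose and 1 fell (1 lower and 60 not called adjusted over the list alone, list adjusted p = 6.65e-10 or 0.517 with an estimated correlation). Among them were L23 (LOC117841533, 0.67 ± 0.10) and L36-3 (LOC117859173, 0.95 ± 0.14). Against their list, an L18a-like protein fell. The 144 pathogenesis-related proteins and chitinases held 67 that rose and 8 that fell (69 and 8 adjusted over the list alone, list adjusted p = 4.17e-08 or 0.278 with an estimated correlation). Chitinase 2 (LOC117833954, 2.59 ± 0.14) and a glucan endo-1,3-beta-glucosidase (LOC117855008, 1.65 ± 0.11), both of which cleave fungal wall polymers, rose. Of 80 genes of the TCA cycle and respiratory chain, 47 rose and 2 fell (48 and 2 adjusted over the list alone, list adjusted p = 4.17e-08 or 0.278 with an estimated correlation). They included citrate synthase 4 (LOC117862245, 0.74 ± 0.07) and, by its name only, NADP isocitrate dehydrogenase (LOC117847610, 0.92 ± 0.07). In the other direction, succinate dehydrogenase assembly factor 1 and 2-oxoglutarate dehydrogenase fell. Among 88 class III peroxidases, 42 rose and 8 fell (42 and 8 adjusted over the list alone, list adjusted p = 2.45e-05 or 0.305 with an estimated correlation). Peroxidase A2 (LOC117841093, 2.67 ± 0.22) and peroxidase 2 (LOC117850082, 4.30 ± 0.38) rose. The 63 glutathione S-transferases held 29 that rose and 6 that fell (29 and 7 adjusted over the list alone, list adjusted p = 0.000115 or 0.276 with an estimated correlation). DHAR1 (LOC117850548, 0.90 ± 0.08), which regenerates ascorbate, and GST 23 (LOC117857520, 1.19 ± 0.11) rose.

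Among 72 WRKY transcription factors, 32 rose and 7 fell (33 and 7 adjusted over the list alone, list adjusted p = 0.000206 or 0.374 with an estimated correlation). For example, WRKY24 (LOC117847284, 2.01 ± 0.20) rose. Of 119 lignin and phenylpropanoid genes, 54 rose and 19 fell (56 and 19 adjusted over the list alone, list adjusted p = 0.00253 or 0.393 with an estimated correlation). The 539 NLR and receptor kinases held 199 that rose and 99 that fell (207 and 102 adjusted over the list alone, list adjusted p = 0.00558 or 0.520 with an estimated correlation). Among 41 jasmonate genes, 16 rose and 4 fell (17 and 4 adjusted over the list alone, list adjusted p = 0.00718 or 0.424 with an estimated correlation). By contrast, linoleate 9S-lipoxygenase 4, TIFY 10a, TIFY 11f and TIFY 6b fell. Of 113 heat shock proteins and chaperones, 47 rose and 21 fell (51 and 24 adjusted over the list alone, list adjusted p = 0.00762 or 0.278 with an estimated correlation). Among the ethylene synthesis genes and ERF factors, 39 rose and 22 fell (39 and 22 adjusted over the list alone, list adjusted p = 0.0150 or 0.496 with an estimated correlation). For example, RAP2-3 (LOC117840982, 3.21 ± 0.15) and RAP2-12 (LOC117840983, 2.83 ± 0.19) rose. The 151 lipid transfer, cutin and wax genes held 58 that rose and 31 that fell (58 and 34 adjusted over the list alone, list adjusted p = 0.0150 or 0.581 with an estimated correlation).

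Of 62 glycolysis genes, 25 rose and 12 fell (28 and 12 adjusted over the list alone, list adjusted p = 0.0230 or 0.415 with an estimated correlation). Among 74 phosphate starvation genes, 27 rose and 20 fell (27 and 22 adjusted over the list alone, list adjusted p = 0.0388 or 0.374 with an estimated correlation). For example, the galactolipid enzyme monogalactosyldiacylglycerol synthase 2 (LOC117860076, 4.38 ± 0.31) rose. Of 96 iron and metal homeostasis genes, 42 rose and 22 fell (44 and 27 adjusted over the list alone, list adjusted p = 0.0410 or 0.399 with an estimated correlation). For example, the iron uptake regulator IRON-RELATED TRANSCRIPTION FACTOR 2 (LOC117854697, 3.16 ± 0.29) rose. The 11 terpenoid and diterpene phytoalexin genes held 6 that rose and 0 that fell (6 and 0 adjusted over the list alone, list adjusted p = 0.0463 or 0.399 with an estimated correlation). Other settings ended calls too, with the highest adjusted p in brackets. Out of 12 alternatives, calls were lost in 6 for terpenoids (0.144 by total counts), 3 for iron (0.0886 by total counts), 2 for phosphate (0.0841 without AI2.2-A replicate 4), 1 for ERF factors (0.0548 by total counts), 1 for lipid transfer (0.0518 by total counts), 1 for glycolysis (0.0513 without AI2.2-A replicate 2) and 1 for the clock list given next (0.0515 without AI2.2-A replicate 2).

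Of the auxin response genes, 11 rose and 50 fell (11 and 50 adjusted over the list alone, list adjusted p = 0.000164 or 0.215 with an estimated correlation). Auxin response factor 18 (LOC117852829, -0.97 ± 0.06) and auxin response factor 8 (LOC117863124, -1.38 ± 0.12) fell. Among 56 photosystem and light-harvesting genes, 3 rose and 26 fell (3 and 28 adjusted over the list alone, list adjusted p = 0.000189 or 0.632 with an estimated correlation). Chlorophyll a-b binding protein 7 (LOC117843554) fell by 1.00 ± 0.10 on the log2 scale, and the assembly factor PSA2 (LOC117861212, -0.71 ± 0.08) fell too. Conversely, the root and embryo isozymes of ferredoxin--NADP reductase and chlorophyll a-b binding protein 1 rose. The 17 chlorophyll breakdown and senescence genes held 0 that rose and 11 that fell (0 and 11 adjusted over the list alone, list adjusted p = 0.000339 or 0.215 with an estimated correlation). For example, the cysteine protease SAG39 (LOC117835971, -1.63 ± 0.24) fell. Of 18 circadian clock genes, 4 rose and 8 fell (4 and 8 adjusted over the list alone, list adjusted p = 0.0138 or 0.424 with an estimated correlation). For example, REVEILLE 2 (LOC117833204, -1.65 ± 0.15) fell. Unlike these, PRR73, GIGANTEA, ELF4-LIKE 4 and adagio-like 3 rose. Among 16 brassinosteroid and strigolactone genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone, list adjusted p = 0.0273 or 0.372 with an estimated correlation). Against their list, the receptor BRL3 rose.

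**Figure D2:**
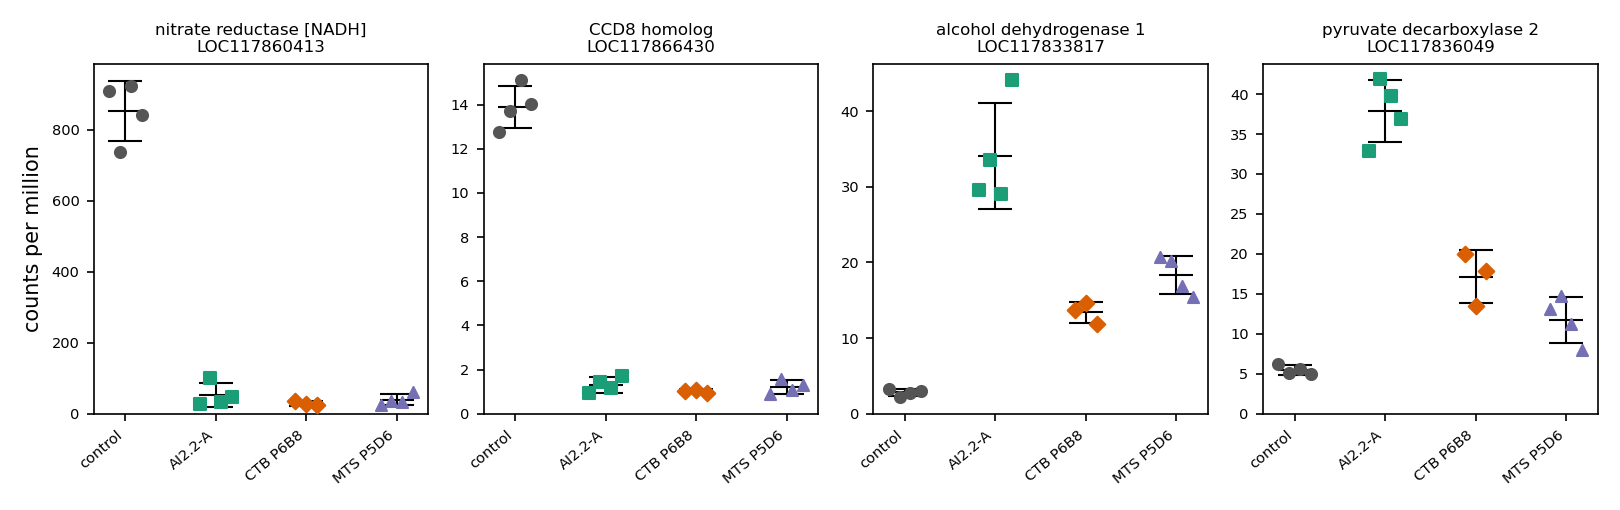
CPM of 4 named genes in each of the 15 libraries, with group means and SD as bars (n = 3 for CTB P6B8 and n = 4 for the other groups). Nitrate reductase and the carotenoid cleavage dioxygenase 8 homolog were lower beside all 3 isolates, and alcohol dehydrogenase 1 and pyruvate decarboxylase 2 were higher, with their largest means beside AI2.2-A (34 and 37.9 CPM).

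Beside CTB P6B8, chitinase transcripts rose and the main nitrate reductase transcript fell. Endochitinase A (LOC117863103, 3.54 ± 0.23) went from 18.6 ± 3.72 in controls to 215 ± 57.8 CPM (SD, n = 4 and 3), and chitinase 2 (LOC117833954, 2.51 ± 0.14) from 24.4 ± 2.98 to 138 ± 7.22 CPM (SD, n = 4 and 3). NADH nitrate reductase (LOC117860413, -4.88 ± 0.43) fell from 853 ± 84.8 to 28.9 ± 6.51 CPM (SD, n = 4 and 3). The fermentation enzymes alcohol dehydrogenase 1 (LOC117833817, 2.24 ± 0.18) and pyruvate decarboxylase 2 (LOC117836049, 1.66 ± 0.18) rose as well. In total 9217 genes (45.4%) changed, 4600 higher and 4617 lower, with 1738 up and 468 down at least 2-fold. The higher share, 49.9%, ran from 49.3% to 63.8% over 16 alternatives and crossed 50% in 10, highest by total counts alone.

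Among transcripts near 0 in controls, TMM-scaled summed counts of NADPH:quinone oxidoreductase 1 (LOC117836940) were 228-fold (95% counting interval 62.7 to 1886) higher. Those of the proline--tRNA ligase-like gene (LOC117860973) were 144-fold (95% counting interval 48.9 to 700.2) higher. The ervatamin-B-like gene (LOC117833743, 8.16 ± 1.77), the 28 kDa phosphoprotein (LOC117850329, 7.25 ± 1.26), indole-2-monooxygenase (LOC117861752, 6.30 ± 1.08) and a FadD32-like fatty acid ligase (LOC117849945, 5.78 ± 0.41), with 10 control counts for the last, rose. Their adjusted p ran from 1.58e-07 to 0.00418, but the protease call was lost in limma-voom (adjusted p = 0.0865) and the ligase call without CTB P6B8 replicate 1 (0.0670). Single libraries carried these folds: without CTB P6B8 replicate 1 the ligase stood at 4.40 in place of 6.95 and the phosphoprotein at 5.30, and without CTB P6B8 replicate 2 the protease stood at 6.01 (8.79 without control replicate 3) and the monooxygenase at 5.03. Lower were carotenoid cleavage dioxygenase 8 (LOC117866430, -3.77 ± 0.21), PELPK1 (LOC117836899, -3.58 ± 0.61), the cation transporter HKT8 (LOC117858061, -3.45 ± 0.39), a laccase-12-like gene (LOC117847269, -2.92 ± 0.20), of a family of lignin-polymerising oxidases, and SWEET14 (LOC117866587, -2.54 ± 0.36), with adjusted p from 4.39e-08 to 0.000221, and PELPK1 stood at -2.94 without control replicate 1.

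Of 144 pathogenesis-related proteins and chitinases, 73 rose and 8 fell (79 and 8 adjusted over the list alone, list adjusted p = 2.29e-10 or 0.250 with an estimated correlation). Among 63 glutathione S-transferases, 32 rose and 6 fell (33 and 6 adjusted over the list alone, list adjusted p = 1.42e-06 or 0.215 with an estimated correlation). GST 23 (LOC117857520, 1.60 ± 0.12) and microsomal GST 3 (LOC117838514, 1.00 ± 0.08) rose. The 72 WRKY transcription factors held 40 that rose and 5 that fell (41 and 5 adjusted over the list alone, list adjusted p = 3.21e-06 or 0.278 with an estimated correlation). WRKY31 (LOC117854979, 1.80 ± 0.17) and WRKY51 (LOC117849840, 1.48 ± 0.14) rose. In the other direction, WRKY46, WRKY4, SUSIBA2, WRKY32 and WRKY14 fell. Of 41 jasmonate genes, 24 rose and 2 fell (24 and 2 adjusted over the list alone, list adjusted p = 5.98e-05 or 0.305 with an estimated correlation). They included 12-oxophytodienoate reductase 5 (LOC117847303, 1.69 ± 0.17) and allene oxide cyclase (LOC117840603, 1.10 ± 0.12), both of jasmonate synthesis. By contrast, linoleate 9S-lipoxygenase 4 and lipoxygenase 2.3 fell. Among 8 genes of the low-oxygen response, 6 rose and 1 fell (6 and 1 adjusted over the list alone, list adjusted p = 2.45e-05 or 0.215 with an estimated correlation). For example, pyruvate decarboxylase 1 (LOC117858936, 2.32 ± 0.26) and alcohol dehydrogenase 1 (LOC117833817, 2.24 ± 0.18) rose. Conversely, the second hemoglobin gene fell. The 80 TCA cycle and respiratory chain genes held 42 that rose and 3 that fell (45 and 3 adjusted over the list alone, list adjusted p = 2.49e-05 or 0.393 with an estimated correlation). Examples were succinate dehydrogenase subunit 5 (LOC117856924, 0.65 ± 0.07) and NADP isocitrate dehydrogenase (LOC117847610, 0.65 ± 0.08). Unlike these, 2 succinate dehydrogenase flavoproteins and 2-oxoglutarate dehydrogenase fell. Of 184 cytosolic ribosomal proteins, 59 rose and 0 fell (44 and 0 adjusted over the list alone, list adjusted p = 0.000199 or 0.689 with an estimated correlation). S27 (LOC117862416, 0.49 ± 0.08) and L17 (LOC117859993, 0.52 ± 0.09) rose.

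Among 113 heat shock proteins and chaperones, 53 rose and 12 fell (55 and 12 adjusted over the list alone, list adjusted p = 0.000256 or 0.215 with an estimated correlation). Of 96 iron and metal homeostasis genes, 38 rose and 15 fell (40 and 15 adjusted over the list alone, list adjusted p = 0.000880 or 0.250 with an estimated correlation). The 74 phosphate starvation genes held 31 that rose and 16 that fell (31 and 16 adjusted over the list alone, list adjusted p = 0.00246 or 0.250 with an estimated correlation). Among 88 class III peroxidases, 35 rose and 9 fell (36 and 9 adjusted over the list alone, list adjusted p = 0.00492 or 0.452 with an estimated correlation). Of 119 lignin and phenylpropanoid genes, 48 rose and 16 fell (48 and 18 adjusted over the list alone, list adjusted p = 0.00972 or 0.415 with an estimated correlation). The lignin call was lost without CTB P6B8 replicate 2 (adjusted p = 0.0564). The 73 flavonoid and anthocyanin genes held 23 that rose and 5 that fell (20 and 2 adjusted over the list alone, list adjusted p = 0.0122 or 0.424 with an estimated correlation). Against their list, 2-hydroxyisoflavanone dehydratase, anthocyanin regulatory C1 protein, anthocyanidin 5,3-O-glucosyltransferase, flavanone 3-dioxygenase 3 and an anthocyanidin glucoside malonyltransferase fell.

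Of 56 photosystem and light-harvesting genes, 1 rose and 30 fell (1 and 31 adjusted over the list alone, list adjusted p = 5.92e-05 or 0.597 with an estimated correlation). Chlorophyll a-b binding protein 7 (LOC117843554, -0.95 ± 0.11) and the assembly factor PSA2 (LOC117848953, -0.86 ± 0.12) fell. In the other direction, chlorophyll a-b binding protein 1 rose. Among the auxin response genes, 16 rose and 54 fell (16 and 54 adjusted over the list alone, list adjusted p = 0.000437 or 0.239 with an estimated correlation). For example, auxin-responsive protein IAA9 (LOC117841458, -1.15 ± 0.18) fell. The 22 chlorophyll synthesis genes held 1 that rose and 9 that fell (1 and 9 adjusted over the list alone, list adjusted p = 0.00398 or 0.424 with an estimated correlation). For example, magnesium chelatase subunit ChlH (LOC117863876, -1.09 ± 0.12) fell. By contrast, mitochondrial protoporphyrinogen oxidase rose. Of 49 cellulose and hemicellulose synthases, 8 rose and 19 fell (8 and 19 adjusted over the list alone, list adjusted p = 0.00802 or 0.452 with an estimated correlation). For example, cellulose synthase A6 (LOC117843743, -1.20 ± 0.10) fell.

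Beside MTS P5D6, transcripts of an expansin, a histone and a fructan synthesis enzyme fell and those of a chaperone rose. Expansin-B3 (LOC117836062, -2.46 ± 0.17), of a wall-loosening family, went from 32.3 ± 3.19 in controls to 5.84 ± 0.609 CPM (SD, n = 4 and 4), and histone H3.2 (LOC117862385, -1.14 ± 0.12) from 17.5 ± 2.49 to 7.91 ± 1.11 CPM (SD, n = 4 and 4). A heat shock 70 kDa protein (LOC117855957, 3.00 ± 0.19) went up from 14.5 ± 3.20 to 116 ± 17.0 CPM (SD, n = 4 and 4). Sucrose:sucrose 1-fructosyltransferase (LOC117861538, -4.39 ± 0.19), the entry step of fructan synthesis, fell from 342 ± 40.8 to 16.3 ± 4.62 CPM (SD, n = 4 and 4). This comparison had the highest count against control, 10598 genes (52.2%), 4847 higher and 5751 lower, with 1710 up and 1096 down at least 2-fold. The higher share, 45.7%, ran from 45.2% to 52.0% over 17 alternatives and crossed 50% in 4, highest with no filter.

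Among transcripts low in controls, the 28 kDa phosphoprotein (LOC117850329, 7.34 ± 1.23), the ervatamin-B-like gene (LOC117833743, 6.86 ± 1.89), an external alternative NAD(P)H dehydrogenase (LOC117855270, 6.76 ± 0.78) of mitochondria, glutaredoxin-C10 (LOC117833974, 6.74 ± 0.72) and the efflux carrier DETOXIFICATION 16 (LOC117865053, 6.74 ± 0.77) rose, with 10, 6, 4, 4 and 69 control counts. TMM-scaled summed counts of the proline--tRNA ligase-like gene (LOC117860973) were 166-fold (95% counting interval 56.5 to 807) higher. Adjusted p ran from 1.93e-06 to 0.00621, and the protease call was lost in limma-voom (adjusted p = 0.131), with a log2 fold change of 6.06 without MTS P5D6 replicate 2 and 7.49 without control replicate 3, while the dehydrogenase stood at 8.04 without control replicate 2. The largest decreases were in the cation transporter HKT8 (LOC117858061, -5.50 ± 0.44), NADH nitrate reductase (LOC117860413, -4.45 ± 0.37), the fructosyltransferase above, a laccase-12-like gene (LOC117856072, -3.93 ± 0.22), carotenoid cleavage dioxygenase 8 (LOC117866430, -3.52 ± 0.19) and the protein kinase CIPK5 (LOC117858243, -3.40 ± 0.19), with adjusted p from 1.79e-09 to 1.89e-07, and HKT8 stood at -6.12 without MTS P5D6 replicate 3.

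Of 113 heat shock proteins and chaperones, 62 rose and 13 fell (63 and 15 adjusted over the list alone, list adjusted p = 4.17e-08 or 0.0632 with an estimated correlation). A 17.9 kDa class I protein (LOC117837276, 1.20 ± 0.07) rose with the 70 kDa protein. Among 72 WRKY transcription factors, 40 rose and 6 fell (41 and 6 adjusted over the list alone, list adjusted p = 1.70e-06 or 0.278 with an estimated correlation). WRKY31 (LOC117854979, 1.79 ± 0.16) and WRKY24 (LOC117847284, 2.08 ± 0.20) rose. The 144 pathogenesis-related proteins and chitinases held 67 that rose and 26 that fell (67 and 27 adjusted over the list alone, list adjusted p = 0.000108 or 0.403 with an estimated correlation). Chitinase 2 (LOC117833954, 2.31 ± 0.14) and the glucan endo-1,3-beta-glucosidase (LOC117855008, 1.43 ± 0.11) rose. Among 63 glutathione S-transferases, 27 rose and 8 fell (28 and 9 adjusted over the list alone, list adjusted p = 0.00113 or 0.305 with an estimated correlation). Of 8 genes of the low-oxygen response, 6 rose and 1 fell (6 and 1 adjusted over the list alone, list adjusted p = 0.00123 or 0.278 with an estimated correlation). For example, alcohol dehydrogenase 1 (LOC117833817, 2.69 ± 0.17) and pyruvate decarboxylase 1 (LOC117858936, 2.61 ± 0.25) rose. Conversely, the second hemoglobin gene fell. Among 41 jasmonate genes, 20 rose and 4 fell (20 and 4 adjusted over the list alone, list adjusted p = 0.00207 or 0.399 with an estimated correlation). Unlike these, lipoxygenase 2.3, linoleate 9S-lipoxygenase 2, GH3.3 and GH3.5 fell.

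The 80 TCA cycle and respiratory chain genes held 30 that rose and 9 that fell (30 and 9 adjusted over the list alone, list adjusted p = 0.00513 or 0.496 with an estimated correlation). Of the ethylene synthesis genes and ERF factors, 49 rose and 18 fell (49 and 18 adjusted over the list alone, list adjusted p = 0.00802 or 0.489 with an estimated correlation). For example, ERF114 (LOC117848219, 2.80 ± 0.22) rose. Among 74 phosphate starvation genes, 28 rose and 18 fell (29 and 18 adjusted over the list alone, list adjusted p = 0.0150 or 0.305 with an estimated correlation). The 96 iron and metal homeostasis genes held 35 that rose and 21 that fell (35 and 23 adjusted over the list alone, list adjusted p = 0.0440 or 0.399 with an estimated correlation). The iron call was lost in 5 of 12 alternatives (highest adjusted p = 0.0823, without control replicate 4).

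Of 56 photosystem and light-harvesting genes, 2 rose and 40 fell (2 and 44 adjusted over the list alone, list adjusted p = 5.02e-07 or 0.496 with an estimated correlation). They included PSB27-H1 (LOC117838489, -0.67 ± 0.08), of photosystem II repair, and photosystem I subunit N (LOC117865346, -1.10 ± 0.13). Against their list, psbP domain proteins 7 and 5 rose. Among the auxin response genes, 13 rose and 71 fell (13 and 72 adjusted over the list alone, list adjusted p = 9.94e-06 or 0.215 with an estimated correlation). Auxin transporter 1 (LOC117855244, -1.30 ± 0.08) and the efflux carrier PIN1a (LOC117837799, -1.40 ± 0.09) fell. The 49 cellulose and hemicellulose synthases held 6 that rose and 30 that fell (7 and 31 adjusted over the list alone, list adjusted p = 2.16e-05 or 0.278 with an estimated correlation). Cellulose synthase A6 (LOC117843743, -1.23 ± 0.09) and A1 (LOC117849548, -0.75 ± 0.06) fell. Of 183 histone and cell cycle genes, 14 rose and 104 fell (16 and 109 adjusted over the list alone, list adjusted p = 2.28e-05 or 0.393 with an estimated correlation). The kinesin KIN-14L (LOC117854027, -0.92 ± 0.07) fell with histone H3.2. Among 27 expansins, 2 rose and 14 fell (2 and 14 adjusted over the list alone, list adjusted p = 0.000264 or 0.372 with an estimated correlation). Another expansin-B3 (LOC117837027, -2.33 ± 0.16) fell with the one above. In the other direction, expansin A2 and expansin B1 rose.

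Of 22 chlorophyll synthesis genes, 1 rose and 12 fell (1 and 12 adjusted over the list alone, list adjusted p = 0.000994 or 0.399 with an estimated correlation). For example, glutamyl-tRNA reductase 2 (LOC117838070, -1.30 ± 0.11) fell. By contrast, mitochondrial protoporphyrinogen oxidase rose. Among 46 growth-regulating factor and meristem genes, 1 rose and 25 fell (2 and 25 adjusted over the list alone, list adjusted p = 0.00543 or 0.399 with an estimated correlation). For example, LOB domain protein 37 (LOC117840802, -2.27 ± 0.25) fell. Conversely, LOB domain protein 42 rose. The 151 lipid transfer, cutin and wax genes held 24 that rose and 73 that fell (25 and 74 adjusted over the list alone, list adjusted p = 0.00788 or 0.520 with an estimated correlation). Of 13 root tissue markers, 0 rose and 8 fell (1 and 8 adjusted over the list alone, list adjusted p = 0.0150 or 0.215 with an estimated correlation). For example, root phototropism protein 2 (LOC117833311, -1.47 ± 0.19) fell. The root marker list, picked by name and not tested for tissue, had adjusted p of 0.215 beside AI2.2-A and 0.0793 beside CTB P6B8. Among 34 xyloglucan endotransglucosylases, 2 rose and 17 fell (2 and 17 adjusted over the list alone, list adjusted p = 0.0395 or 0.489 with an estimated correlation). Unlike these, xyloglucan endotransglucosylases 23 and 24 rose. The last call was lost without control replicate 3 (adjusted p = 0.0538) or MTS P5D6 replicate 2 (0.0674) or 3 (0.0572).

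**Figure D3:**
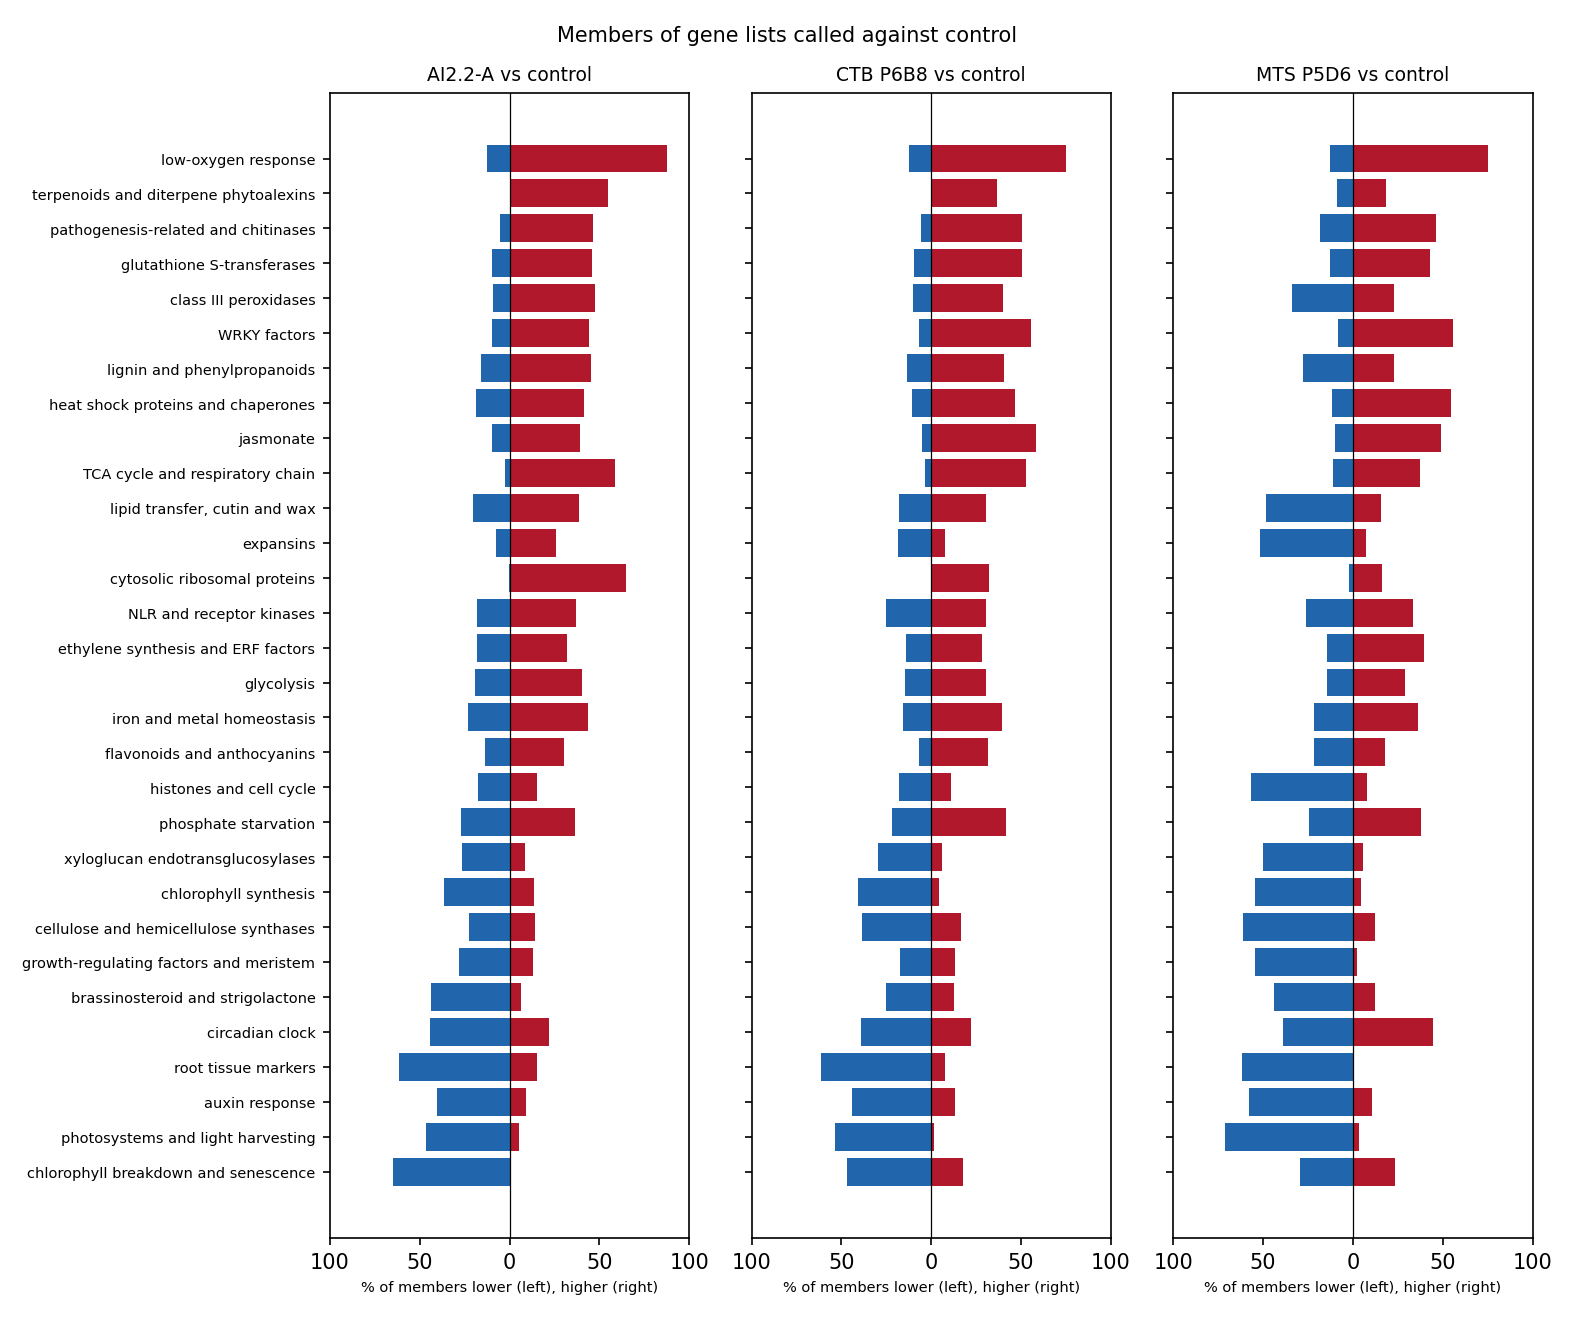
Percent of tested members higher (right, red) and lower (left, blue) in the 30 gene lists called against control beside at least 1 isolate, 1 panel per isolate. Photosystem and auxin lists extend to the left in all 3 panels, and expansins and cell cycle genes extend far to the left in the MTS P5D6 panel (2 higher and 14 lower of 27 expansins).

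The other 14 lists were not called against control beside any isolate. Their counts follow for AI2.2-A, then CTB P6B8, then MTS P5D6. C4 shuttle and Calvin cycle genes (50 tested) had 20 higher and 16 lower, 16 and 18, and 14 and 17, or 20 and 16, 16 and 18, and 14 and 19 adjusted over the list alone (list adjusted p from 0.443 to 0.875). Photorespiration genes (31 tested) had 13 higher and 7 lower, 7 and 6, and 5 and 9, or 13 and 7, 6 and 5, and 5 and 9 adjusted over the list alone (list adjusted p from 0.383 to 0.882). Starch and sucrose genes (109 tested) had 26 higher and 40 lower, 25 and 33, and 25 and 34, or 27 and 42, 26 and 33, and 25 and 34 adjusted over the list alone (list adjusted p from 0.305 to 0.322). Pectin-modifying genes (88 tested) had 27 higher and 16 lower, 23 and 16, and 14 and 33, with the same counts adjusted over the list alone (list adjusted p from 0.224 to 0.414). Cytokinin genes (48 tested) had 10 higher and 13 lower, 9 and 12, and 12 and 17, or 10 and 13, 9 and 12, and 13 and 17 adjusted over the list alone (list adjusted p from 0.560 to 0.990). Gibberellin genes (29 tested) had 11 higher and 4 lower, 10 and 3, and 12 and 9, or 11 and 4, 11 and 4, and 14 and 9 adjusted over the list alone (list adjusted p from 0.298 to 0.759). Abscisic acid and dehydration genes (131 tested) had 26 higher and 39 lower, 33 and 31, and 46 and 37, or 27 and 41, 34 and 33, and 47 and 38 adjusted over the list alone (list adjusted p from 0.181 to 0.710).

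Antioxidant enzymes (37 tested) had 17 higher and 12 lower, 14 and 11, and 14 and 10, or 18 and 12, 14 and 11, and 15 and 10 adjusted over the list alone (list adjusted p from 0.141 to 0.729). Nitrogen uptake and assimilation genes (86 tested) had 24 higher and 23 lower, 28 and 20, and 23 and 26, or 24 and 24, 28 and 21, and 24 and 27 adjusted over the list alone (list adjusted p from 0.560 to 0.826). Sulfur uptake and assimilation genes (31 tested) had 8 higher and 10 lower, 7 and 7, and 6 and 9, or 8 and 11, 7 and 7, and 6 and 9 adjusted over the list alone (list adjusted p from 0.318 to 0.824). Chloroplast ribosomal proteins (76 tested) had 14 higher and 5 lower, 10 and 10, and 6 and 17, or 11 and 2, 7 and 9, and 5 and 14 adjusted over the list alone (list adjusted p from 0.443 to 0.729). Aquaporins (25 tested) had 3 higher and 1 lower, 9 and 0, and 5 and 12, or 0 and 0, 9 and 0, and 5 and 12 adjusted over the list alone (list adjusted p from 0.181 to 0.864). Seed tissue markers (9 tested) had 2 higher and 1 lower, 3 and 0, and 5 and 0, with the same counts adjusted over the list alone (list adjusted p from 0.0525 to 0.329). Stress and RNA quality markers (27 tested) had 6 higher and 9 lower, 8 and 5, and 13 and 5, or 6 and 9, 9 and 6, and 13 and 5 adjusted over the list alone (list adjusted p from 0.0509 to 0.544).

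Beside all 3 isolates, 2274 genes rose and 2539 fell, and 145 were called in mixed directions. Ranked by their smallest increase, the first 4 were the ervatamin-B-like gene, the proline--tRNA ligase-like gene, the 28 kDa phosphoprotein and indole-2-monooxygenase (LOC117861752, 5.42 ± 1.12 beside MTS P5D6). Nitrate reductase, carotenoid cleavage dioxygenase 8, PELPK1 (LOC117836899, -3.04 ± 0.52 beside MTS P5D6, -2.40 without control replicate 1) and SWEET14 (LOC117866587, -3.23 ± 0.35) led the shared decreases. For AI2.2-A and CTB P6B8, 3292 genes rose in both and 3428 fell, where independent lists would share 1074 and 1124, and 33 were called in opposite directions. Log2 fold changes had r = 0.846 and covariance 0.482 across genes, 0.507 and 0.0356 in simulated unchanged groups, and 0.742 and 0.489 with split controls. For AI2.2-A and MTS P5D6, 2616 genes rose in both and 2930 fell, where independent lists would share 1132 and 1400, and 561 were called in opposite directions. Log2 fold changes had r = 0.674 and covariance 0.420 across genes, 0.535 and 0.0354 in simulated unchanged groups, and 0.595 and 0.423 with split controls. For CTB P6B8 and MTS P5D6, 3105 genes rose in both and 3255 fell, where independent lists would share 1098 and 1307, and 178 were called in opposite directions. Log2 fold changes had r = 0.803 and covariance 0.518 across genes, 0.501 and 0.0360 in simulated unchanged groups, and 0.716 and 0.525 with split controls. In the 20 simulations 0 calls by edgeR were shared, with a mean of 119.7 to 132 shared higher and 134 to 145 shared lower at an unadjusted p under 0.05. Shared controls add a covariance like the simulated one, so most of the observed covariance did not come from shared control error, although any difference of the 4 controls as a group from all isolate plates enters every pair. Genes are not independent replicates.

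In AI2.2-A against CTB P6B8, alcohol dehydrogenase 1 (LOC117833817, 1.35 ± 0.15) and pyruvate decarboxylase 2 (LOC117836049, 1.14 ± 0.16) were higher with AI2.2-A, with adjusted p of 0.000230 and 0.00115. So were the transporter ZIFL1 (LOC117847851, 3.75 ± 0.84), lipoxygenase 2.1 (LOC117851960, 2.91 ± 0.55) and nicotianamine synthase 2 (LOC117840190, 2.61 ± 0.59), of metal chelator synthesis. A chloroplast thioredoxin-like 1-1 (LOC117836971, -2.05 ± 0.39), mannan endo-1,4-beta-mannosidase 3 (LOC117837010, -1.99 ± 0.46) and a 16.9 kDa class I heat shock protein (LOC117857321, -1.90 ± 0.38) were lower. This direct test changed 2110 genes (10.4%), 920 higher and 1190 lower with AI2.2-A, and 174 and 219 of them at least 2-fold. The higher share, 43.6%, ran from 33.6% to 53.4% over 16 alternatives and crossed 50% in 1, by total counts alone. The count was 644 without CTB P6B8 replicate 2, 1020 without AI2.2-A replicate 1, 1282 without AI2.2-A replicate 3 and 871 with both groups fitted alone, and without CTB P6B8 replicate 2 the adjusted p was 0.0610 for ZIFL1, 0.0610 for nicotianamine synthase and 0.111 for the mannosidase, whose log2 fold change was -1.06, and that of the thioredoxin -1.38, while nicotianamine synthase stood at 3.50 without CTB P6B8 replicate 3.

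Low-oxygen genes had 4 higher and 0 lower of 8 (5 and 0 adjusted over the list alone, list adjusted p = 2.69e-07 or 0.266 with an estimated correlation), led by alcohol dehydrogenase 2 (LOC117834143, 2.18 ± 0.20). Among 539 NLR and receptor kinases, led by cysteine-rich receptor-like kinase 10 (LOC117845217, 1.71 ± 0.15), 45 were higher and 4 lower (44 and 4 adjusted over the list alone, list adjusted p = 5.73e-05 or 0.558 with an estimated correlation). Cellulose and hemicellulose synthases had 10 higher and 0 lower of 49 (11 and 2 adjusted over the list alone, list adjusted p = 0.000151 or 0.398 with an estimated correlation), led by cellulose synthase A6 (LOC117843743, 0.80 ± 0.10). Among 22 chlorophyll synthesis genes, led by chloroplast protoporphyrinogen oxidase (LOC117858503, 0.34 ± 0.10), 1 was higher and 0 lower (0 and 0 adjusted over the list alone, list adjusted p = 0.0255 or 0.596 with an estimated correlation). Other lists higher with AI2.2-A were cytosolic ribosomal proteins with 6 higher and 1 lower of 184 (0 and 0 adjusted over the list alone) and histone and cell cycle genes with 20 higher and 8 lower of 183 (44 and 13 adjusted over the list alone). The list adjusted p were 0.000153 and 0.00367, with adjusted p = 0.771 and 0.596 with an estimated correlation. Against the ribosomal list went an L18a-like protein. They were followed by expansins with 7 higher and 2 lower of 27 (10 and 2 adjusted over the list alone) and class III peroxidases with 8 higher and 2 lower of 88 (9 and 2 adjusted over the list alone). These lists had adjusted p of 0.0174 and 0.0308, with adjusted p = 0.588 and 0.607 with an estimated correlation. The other way went expansins A2 and A1 and peroxidases 64 and 16.

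Lists lower with AI2.2-A than with CTB P6B8 came next. Chlorophyll breakdown and senescence genes had 0 higher and 3 lower of 17 (0 and 4 adjusted over the list alone, list adjusted p = 0.00273 or 0.266 with an estimated correlation), led by STAY-GREEN (LOC117843798, -0.80 ± 0.18), the chlorophyll b reductase NYC1 (LOC117857330, -0.75 ± 0.17) and SENESCENCE-ASSOCIATED GENE 21 (LOC117857398, -0.52 ± 0.15). Among 18 clock genes, led by REVEILLE 2 (LOC117833204, -0.57 ± 0.16) and ELF4-LIKE 4 (LOC117840261, -0.38 ± 0.10), 0 were higher and 2 lower (0 and 3 adjusted over the list alone, list adjusted p = 0.0347 or 0.588 with an estimated correlation). Lower as well were stress and RNA quality markers with 0 higher and 5 lower of 27 (0 and 6 adjusted over the list alone) and abscisic acid and dehydration genes with 3 higher and 12 lower of 131 (3 and 15 adjusted over the list alone). Their list tests gave adjusted p of 0.0124 and 0.0228, with adjusted p = 0.266 and 0.381 with an estimated correlation. Called last were aquaporins with 0 higher and 8 lower of 25 (2 and 8 adjusted over the list alone), jasmonate genes with 2 higher and 7 lower of 41 (2 and 10 adjusted over the list alone) and iron and metal homeostasis genes with 3 higher and 16 lower of 96 (4 and 22 adjusted over the list alone). As lists, their adjusted p were 0.0329, 0.0338 and 0.0445, with adjusted p = 0.512, 0.596 and 0.512 with an estimated correlation. Opposite in sign came lipoxygenases 2.3 and 2.1. Out of 11 alternatives, calls were lost in 6 for peroxidases (0.168 without CTB P6B8 replicate 1), 4 for the clock (0.114 without AI2.2-A replicate 2), 4 for iron (0.124 without AI2.2-A replicate 4), 3 for chlorophyll synthesis (0.261 without CTB P6B8 replicate 2), 3 for jasmonate (0.180 without CTB P6B8 replicate 2), 3 for expansins (0.0919 without AI2.2-A replicate 2), 2 for ribosomal proteins (0.559 without CTB P6B8 replicate 2), 2 for aquaporins (0.182 without AI2.2-A replicate 4) and 1 for the cell cycle (0.0869 in directional fry).

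In AI2.2-A against MTS P5D6, HKT8 (LOC117858061, 3.62 ± 0.47), a 3-aminomethylindole N-methyltransferase (LOC117867045, 3.55 ± 0.29) of indole alkaloid synthesis and endo-1,4-beta-xylanase 1 (LOC117840455, 3.45 ± 0.35) were higher with AI2.2-A, as were alcohol dehydrogenase 1 (LOC117833817, 0.89 ± 0.14) and sucrose:sucrose 1-fructosyltransferase (LOC117861538, 2.40 ± 0.18). The external alternative NAD(P)H dehydrogenase (LOC117855270, -2.83 ± 0.49), the 16.9 kDa heat shock protein (LOC117857321, -2.74 ± 0.36) and the ubiquitin ligase CIP8 (LOC117843102, -2.53 ± 0.20) were lower, and the 3 higher and 3 lower genes of the naming rule had adjusted p from 5.33e-07 to 0.000260, with HKT8 at 4.24 without MTS P5D6 replicate 3. Here 9178 genes (45.2%) differed, 4832 higher and 4346 lower with AI2.2-A, and 1473 and 638 at least 2-fold. The higher share, 52.6%, ran from 48.3% to 67.1% over 17 alternatives and crossed 50% in 3, lowest in DESeq2 and highest by total counts alone.

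Lipid transfer, cutin and wax genes had 91 higher and 19 lower of 151 (94 and 19 adjusted over the list alone, list adjusted p = 3.33e-09 or 0.300 with an estimated correlation), led by a GDSL esterase/lipase (LOC117856833, 2.39 ± 0.26). Among 183 histone and cell cycle genes, led by histone H2A (LOC117836195, 1.58 ± 0.18), 99 were higher and 18 lower (103 and 19 adjusted over the list alone, list adjusted p = 3.29e-08 or 0.303 with an estimated correlation). Class III peroxidases had 54 higher and 7 lower of 88 (55 and 7 adjusted over the list alone, list adjusted p = 6.02e-08 or 0.266 with an estimated correlation), led by peroxidase 72 (LOC117855212, 2.50 ± 0.17). Among 27 expansins, led by a further expansin-B3 (LOC117835120, 2.27 ± 0.18), 20 were higher and 4 lower (21 and 4 adjusted over the list alone, list adjusted p = 1.25e-07 or 0.266 with an estimated correlation). Also higher with AI2.2-A were cellulose and hemicellulose synthases with 28 higher and 3 lower of 49 (28 and 3 adjusted over the list alone) and cytosolic ribosomal proteins with 83 higher and 2 lower of 184 (85 and 2 adjusted over the list alone). The list adjusted p were 4.49e-06 and 2.38e-05, with adjusted p = 0.299 and 0.736 with an estimated correlation. Against the ribosomal list went an L18a-like protein and 40S ribosomal protein S27. Next came lignin and phenylpropanoid genes with 57 higher and 15 lower of 119 (60 and 17 adjusted over the list alone) and low-oxygen genes with 6 higher and 1 lower of 8 (6 and 1 adjusted over the list alone). These lists had adjusted p of 5.73e-05 and 0.000153, with adjusted p = 0.303 and 0.266 with an estimated correlation. The other way went pyruvate decarboxylase 1. The list test also called pectin-modifying genes with 39 higher and 13 lower of 88 (41 and 13 adjusted over the list alone) and TCA cycle and respiratory chain genes with 30 higher and 10 lower of 80 (32 and 11 adjusted over the list alone). Their list tests gave adjusted p of 0.00415 and 0.0329, with adjusted p = 0.435 and 0.657 with an estimated correlation. Nearer the threshold lay chlorophyll synthesis genes with 12 higher and 2 lower of 22 (12 and 2 adjusted over the list alone) and growth-regulating factor and meristem genes with 20 higher and 2 lower of 46 (20 and 2 adjusted over the list alone). As lists, their adjusted p were 0.0391 and 0.0431, with adjusted p = 0.607 and 0.596 with an estimated correlation. Opposite in sign came glutamyl-tRNA reductase-binding protein, mitochondrial protoporphyrinogen oxidase and homeobox proteins knotted-1 11 and 2.

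The remaining lists were lower with AI2.2-A. Heat shock proteins and chaperones had 13 higher and 48 lower of 113 (14 and 51 adjusted over the list alone, list adjusted p = 0.000153 or 0.266 with an estimated correlation), led by another heat shock 70 kDa protein 4 (LOC117848470, -2.15 ± 0.24). Below them in rank were stress and RNA quality markers with 3 higher and 14 lower of 27 (3 and 15 adjusted over the list alone), abscisic acid and dehydration genes with 15 higher and 45 lower of 131 (15 and 45 adjusted over the list alone) and clock genes with 2 higher and 9 lower of 18 (3 and 11 adjusted over the list alone). The list adjusted p were 0.00197, 0.00666 and 0.0338, with adjusted p = 0.266, 0.299 and 0.588 with an estimated correlation. Against the clock list went CCA1 and REVEILLE 6. Over 12 alternatives, calls were lost in 5 for growth-regulating factors (0.101 without AI2.2-A replicate 2), 3 for the TCA cycle (0.0648 without MTS P5D6 replicate 2), 3 for the clock (0.0594 without MTS P5D6 replicate 4) and 2 for chlorophyll synthesis (0.0937 without MTS P5D6 replicate 1).

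In CTB P6B8 against MTS P5D6, NADPH:quinone oxidoreductase 1 (LOC117836940, 3.88 ± 0.52), sucrose:sucrose 1-fructosyltransferase (LOC117861538, 3.00 ± 0.19) and RAFTIN 1A (LOC117860011, 2.83 ± 0.39) were higher with CTB P6B8. The external alternative NAD(P)H dehydrogenase (LOC117855270, -2.12 ± 0.51), EIN3-binding F-box protein 1 (LOC117852716, -1.95 ± 0.51) of ethylene signalling and a DnaJ chaperone (LOC117859867, -1.77 ± 0.36) were lower, and all 6 had adjusted p from 5.60e-07 to 0.0108. The F-box call was lost without CTB P6B8 replicate 3 (adjusted p = 0.0606) and the dehydrogenase call with a block by the numbers in the descriptions (0.0605). The test called 5347 genes (26.3%), 3096 higher and 2251 lower with CTB P6B8, and 925 and 172 at least 2-fold, but 3345 without CTB P6B8 replicate 3 and 2786 with that block. The higher share, 57.9%, ran from 49.4% to 72.7% over 16 alternatives and crossed 50% in 1, lowest in DESeq2 and highest by total counts alone.

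Among 151 lipid transfer, cutin and wax genes, led by 3-ketoacyl-CoA synthase 5 (LOC117855247, 2.08 ± 0.23), 71 were higher and 6 lower (77 and 10 adjusted over the list alone, list adjusted p = 6.49e-11 or 0.266 with an estimated correlation). Class III peroxidases had 37 higher and 7 lower of 88 (44 and 9 adjusted over the list alone, list adjusted p = 2.93e-07 or 0.266 with an estimated correlation), led by peroxidase A2 (LOC117841093, 1.77 ± 0.22). Among 27 expansins, led by a further expansin-B3 (LOC117835120, 1.62 ± 0.19), 14 were higher and 0 lower (14 and 0 adjusted over the list alone, list adjusted p = 8.06e-07 or 0.266 with an estimated correlation). Higher with CTB P6B8 too were histone and cell cycle genes with 71 higher and 7 lower of 183 (78 and 10 adjusted over the list alone) and lignin and phenylpropanoid genes with 45 higher and 5 lower of 119 (48 and 7 adjusted over the list alone). These lists had adjusted p of 2.97e-06 and 3.07e-06, with adjusted p = 0.435 and 0.266 with an estimated correlation. A further pair was aquaporins with 11 higher and 2 lower of 25 (13 and 2 adjusted over the list alone) and pectin-modifying genes with 29 higher and 5 lower of 88 (29 and 5 adjusted over the list alone). Their list tests gave adjusted p of 0.000123 and 0.00125, with adjusted p = 0.266 and 0.381 with an estimated correlation. The other way went aquaporin PIP2-7 and TIP4-2. Called besides were flavonoid and anthocyanin genes with 27 higher and 3 lower of 73 (28 and 3 adjusted over the list alone) and growth-regulating factor and meristem genes with 15 higher and 2 lower of 46 (16 and 2 adjusted over the list alone). As lists, their adjusted p were 0.00238 and 0.00260, with adjusted p = 0.435 and 0.435 with an estimated correlation. Opposite in sign came protein CUP-SHAPED COTYLEDON 2 and homeobox protein knotted-1 11.

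Smaller margins belonged to cellulose and hemicellulose synthases with 15 higher and 2 lower of 49 (17 and 3 adjusted over the list alone) and pathogenesis-related proteins and chitinases with 35 higher and 5 lower of 144 (35 and 5 adjusted over the list alone). The list adjusted p were 0.00925 and 0.0112, with adjusted p = 0.588 and 0.607 with an estimated correlation. Against their lists went COBRA 7 and cellulose synthase D2. Closest to the threshold were cytosolic ribosomal proteins with 20 higher and 1 lower of 184 (6 and 0 adjusted over the list alone) and xyloglucan endotransglucosylases with 14 higher and 4 lower of 34 (14 and 4 adjusted over the list alone). These lists had adjusted p of 0.0329 and 0.0445, with adjusted p = 0.809 and 0.588 with an estimated correlation. The other way went an L18a-like protein. Chaperones were the one list lower with CTB P6B8. Heat shock proteins and chaperones had 9 higher and 31 lower of 113 (11 and 35 adjusted over the list alone, list adjusted p = 0.00103 or 0.266 with an estimated correlation), led by the DnaJ chaperone (LOC117859867, -1.77 ± 0.36). Across 11 alternatives, calls were lost in 6 for ribosomal proteins (0.737 without CTB P6B8 replicate 3), 6 for xyloglucan enzymes (0.113 without CTB P6B8 replicate 2) and 2 for pathogenesis-related proteins (0.230 without CTB P6B8 replicate 2).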

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

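The tests of a wrong label and of a mixed library for AI2.2-A replicate 4 were chosen only after its position was seen. The rule for distant libraries was fixed in advance, and it divides a library's gap to its nearest neighbour by the range of its group.

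Of 222 sets of 4 libraries tested for named genes, 8 held a library beyond Dixon's 95% critical ratio for 4 libraries, where chance gives about 1 in 20. In log2 CPM with a prior count of 2, SWEET14 (LOC117866587) stood at 4.15 in control replicate 2 and 3.38 to 3.51 in the other 3 libraries (ratio 0.832). RAFTIN 1A (LOC117860011) stood at -0.30 in control replicate 2 and 0.67 to 0.81 in the other 3 libraries (ratio 0.869). Peroxidase 2 (LOC117850082) stood at -2.27 in control replicate 4 and -1.29 to -1.18 in the other 3 libraries (ratio 0.9001). Chlorophyll a-b binding protein 7 (LOC117843554) stood at 3.72 in AI2.2-A replicate 3 and 4.01 to 4.06 in the other 3 libraries (ratio 0.871). With MTS P5D6, the FadD32-like ligase (LOC117849945) stood at 2.47 in replicate 2 and 3.50 to 3.64 in the other 3 libraries (ratio 0.880). Ribosomal protein L36-3 (LOC117859173) stood at 4.80 in MTS P5D6 replicate 2 and 4.31 to 4.36 in the other 3 libraries (ratio 0.891). WRKY31 (LOC117854979) stood at 4.38 in MTS P5D6 replicate 2 and 4.98 to 5.06 in the other 3 libraries (ratio 0.874). The assembly factor PSA2 (LOC117848953) stood at 5.05 in MTS P5D6 replicate 1 and 5.45 to 5.53 in the other 3 libraries (ratio 0.838).

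AI2.2-A replicate 4 lay toward the CTB P6B8 libraries: on an axis from the CTB P6B8 mean at 0 to the AI2.2-A mean at 1, over 2464 genes called without it, it stood at 0.533, above held-out CTB P6B8 libraries at 0.0539 to 0.395 by less than their SD (0.189) and below the other AI2.2-A libraries at 0.725 to 1.08. With references matched (AI2.2-A replicates 1 to 3 against 2 CTB P6B8 libraries, 1171 to 2212 genes), it was nearer AI2.2-A in 55.9% to 64.6% of genes and the third CTB P6B8 library in 8.45% to 27.1% (SD 9.33), which argues against a mislabelled CTB P6B8 library, while a label from elsewhere was not tested. For a mixed library, the CTB P6B8 share was 0.598 ± 0.0871 from genes higher with AI2.2-A and 0.330 ± 0.108 from genes lower (SD over 9 pairs of reference libraries), a difference of 0.268 ± 0.0825. That passed the 2 SD bound of this test, but mixtures made from these libraries, expected near 0, gave -0.252 to 0.210 (SD 0.157, 9 mixtures), so a mixed library stays open, and a plant that responded less, which the design allows, was not tested. Without this library the groups differed in 2464 genes in place of 2110.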

How the results depend on the processing

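The alternative memberships of 3 lists were tests chosen only after the data were seen, and the other alternatives were fixed in advance. No named gene and no called list turned its direction under any alternative, but the majority direction of calls did in 5, 10, 4, 1, 3 and 1 of 17, 16, 17, 16, 17 and 16 alternatives, in the order given below. Named genes kept their call in 1731 of their alternative fits and lost it in 14, lists kept their side of the threshold in 3007, gained a call in 129 and lost one in 182, and counts of genes stayed within 1.5 times in 97 and moved further in 14. Counts follow the order AI2.2-A, CTB P6B8, MTS P5D6 against control, then AI2.2-A against CTB P6B8, AI2.2-A against MTS P5D6 and CTB P6B8 against MTS P5D6. The counts of 9687, 9217, 10598, 2110, 9178 and 5347 became 9587, 9180, 10532, 2136, 9247 and 5607 with relative log expression scaling, 9623, 9220, 10462, 2764, 9272 and 5829 in DESeq2 and 10971, 10388, 11133, 2913, 9488 and 5449 in limma-voom. Requiring a 2-fold change, the counts were 2143, 2206, 2806, 393, 2111 and 1097. At an adjusted p under 0.01, AI2.2-A against CTB P6B8 gave 489 and CTB P6B8 against MTS P5D6 2574, and AI2.2-A against CTB P6B8 fitted alone gave 871. Leaving out each replicate gave 8314 to 9483, 7696 to 8497, 9518 to 10413, 644 to 2464, 7662 to 9242 and 3345 to 4775 genes. With camera 22, 17, 20, 15, 16 and 14 lists were called, and 19 to 22, 17 to 20, 19 to 23, 13 to 19, 13 to 17 and 12 to 17 with a replicate left out. With an estimated correlation camera called 1, 0, 0, 0, 0 and 0, with 7, 8, 6, 3, 10 and 6 at an unadjusted p under 0.05, and directional fry called 34, 29, 33, 13, 31 and 22. At an adjusted p under 0.01, AI2.2-A and CTB P6B8 shared 2117 higher and 2239 lower calls, AI2.2-A and MTS P5D6 1740 and 1918, and with the controls split AI2.2-A and CTB P6B8 shared a mean of 2120 higher calls. Libraries that share a replicate number did not deviate together (mean r -0.00697 across genes over 21 pairs, 1 over 0.1, 2 of 15 libraries best with their own number), which does not exclude a batch shared by number. A replicate block gave 9318, 8439, 10291, 1979, 8777 and 4140 genes with the title's numbers and 9167, 8490, 9324, 1858, 7282 and 2786 with the numbers in the descriptions, which differ for MTS P5D6. With AI2.2-A and CTB P6B8 fitted alone, adjusted p was 0.0554 for ZIFL1 (LOC117847851), 0.0546 for nicotianamine synthase 2 (LOC117840190) and 0.0694 for the mannosidase (LOC117837010), and in limma-voom it was 0.154 for ZIFL1. The causes of these changes were not tested, apart from the fewer samples or stricter thresholds themselves. Photorespiration, abscisic acid and cytokinin lists without unrelated members kept their side of the threshold in all 6 comparisons. Of the 35 splits of the libraries of each comparison, 1, the real one, gave as many genes. So few splits cannot exclude chance over 6 comparisons. The highest other splits gave 1, 3570, 3, 1310, 0 and 1078 genes. In edgeR at an unadjusted p under 0.05 the highest other splits gave 4883, 7355, 4506, 4775, 5583 and 5314 genes. The splits with 3570, 1310 and 1078 genes kept all but 1 library of a group together, and that with 1310 placed AI2.2-A replicate 4 with CTB P6B8. Depth limits the genes with few control counts.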

Other observations

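The tests of scaling and of harvest time for the nitrogen genes, and the 3 tests of the authors' deposited control tables, were chosen only after the results were seen, and the genes named here after their values were.

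Both nitrate reductases and the nitrite reductase, which turn nitrate into ammonium, fell and 4 of 5 ammonium transporters rose beside all 3 isolates, while other genes of the nitrogen list went both ways and the list was not called. Log2 fold changes ± SE beside AI2.2-A, then CTB P6B8, then MTS P5D6 were -4.04 ± 0.36, -4.88 ± 0.43 and -4.45 ± 0.37 for NADH nitrate reductase (LOC117860413), -1.93 ± 0.50, -2.01 ± 0.56 and -1.77 ± 0.51 for the NAD(P)H form (LOC117839581) and -2.04 ± 0.15, -2.21 ± 0.17 and -2.20 ± 0.15 for nitrite reductase (LOC117839299). AMT3 member 2 (LOC117835930) rose by 1.75, 1.85 and 1.87, AMT2 member 1 (LOC117846954) by 1.38, 1.84 and 1.60, AMT2 member 3 (LOC117857106) by 2.33, 2.10 and 2.38 and AMT1 member 1 (LOC117865252) by 0.62, 0.76 and 0.40, and AMT3 member 3 (LOC117857427), not called, stood at -0.35, -0.18 and -0.68. Later steps had no single direction: ferredoxin-dependent glutamate synthase (LOC117843736) stood at -1.31, -1.86 and -1.65, NADH glutamate synthase 2 (LOC117848374) at -1.85, -0.88 and 0.38, chloroplast glutamine synthetase (LOC117850814) at -0.34, -0.76 and -0.97, and its cytosolic isozymes 1-1 (LOC117837154) at 0.66, 0.96 and 1.13 and 1-3 (LOC117838069) at 0.17, 0.91 and 2.16 and root isozyme 5 (LOC117840799) at 0.90, 0.69 and 0.35. The nitrate transporter activator NAR2.1 (LOC117860105) stood at 0.82, 1.26 and 2.22.

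Scaling is argued against for this pattern, since the nitrate reductase change nearest 0 under other scalings was -3.91 and 4 of 5 transporters stayed called as higher. Harvest at another time of day stays open, because the labels give no harvest times. Clock genes were sorted into a morning and an evening set by name, and their time of peak was not tested. Of 5 morning genes, 5 fell beside each isolate (medians -0.77, -0.86 and -1.09). Of 9 evening genes, 3, 4 and 5 rose and 3, 2 and 2 fell (medians -0.14, 0.55 and 0.38). In the evening set, GIGANTEA and adagio-like 3 rose beside all 3 isolates, and adagio-like 1 and 2 fell beside all 3. A morning minus evening index, in log2, was 2.27 ± 0.142 in controls (SD, n = 4), 1.24 ± 0.133 with AI2.2-A (n = 4), 1.14 ± 0.196 with CTB P6B8 (n = 3) and 0.761 ± 0.0883 with MTS P5D6 (n = 4). Taken as deviations from group means, it correlated with nitrate reductase over 11 isolate libraries at r = 0.401 (permutation p = 0.236) and rho = 0.327 (permutation p = 0.356), with r = 0.319 over 9 without the 2 farthest, and a miss of the threshold does not exclude it. The isolates' volatiles, which the design names, stay open too and were not tested.

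The authors' deposited tables held 10097, 9507 and 11043 genes at an adjusted p under 0.05 against control for AI2.2-A, then CTB P6B8, then MTS P5D6, of which 9214, 8705 and 9981 were also called here, all with the same sign. Between isolates, the authors' deposited table had 2807, 9390 and 5987 genes, for AI2.2-A against CTB P6B8 and each of them against MTS P5D6.

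Log2 fold changes in the authors' deposited tables correlated with those from the counts, across genes, at r = 0.991, 0.991 and 0.992 against control and departed far less between isolates. Over 17024 genes with a mean log2 CPM of at least 1, slopes on the edgeR values were 0.958, 0.962 and 0.977 against control but 1.00 at the lowest between isolates, which argues against a shrinkage of the folds in all tables. Fits with some of the 4 controls left out are argued against too, as differences of mean log2 CPM over these genes correlated with the authors' deposited tables at 0.992, 0.990 and 0.994 with all 4 controls and at most at 0.988, 0.987 and 0.991 with any left out. The departures of the 3 control tables correlated at 0.999 at the lowest, but their small size between isolates fixes that value, so it decides nothing. A control level that differed from the mean of these 4 libraries stays open, and its origin was not analysed here.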
